A study of Mus musculus with 12 samples.

How the data were processed

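RNA of whole liver was sequenced from 12 mice of 3 groups, 4 per group: Het controls, Atp7b-/- mice (KO), and Atp7b-/- mice fed an agonist of the liver X receptors (KO_drug). The labels give the strain (C57BL/6x129S6/SvEv), the genotype and the age (20 wk). They do not give the sex, the litter, the name, dose or duration of the agonist, or the part of Atp7b that the knockout allele lacks. Per the labels' protocols, RNA was taken from flash-frozen liver with the RNeasy mini kit and made into libraries with the TruSeq Stranded Total RNA kit. Per the submitters' processing notes, FastQC 0.11.7, StringTie 2.1.3b and genome build mm10 were used; the aligner and the annotation release are not given in the sources used here.

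The authors deposited a table of 24532 genes with a read count per gene and library, in whole numbers and not normalized, per the file headers. The same table holds an FPKM per gene and library, deposited by the authors (fragments per kilobase of gene model and 1e6 fragments). Over 6393 genes with at least 200 counts, 99.1% of the ratios of FPKM to count lay within 5% of 1 factor per library. The main tests used the counts, and the deposited FPKM served as an alternative. In the table, 3 columns without a name hold values for 4 genes and are not used here. Of the 24532 genes, 24462 (99.7%) were matched by gene number to a RefSeq table for their position and kind. In some libraries the deposited counts may assign reads of near-identical or overlapping genes to 1 of them, since Adnp and the read-through gene Dpm1-adnp were at 0 in turn in KO 4 and KO 2. Both were counted in KO_drug 3, Het 2 and KO 6, so this is not general. Values of single members of the Mup, Cyp2a, Cyp2c, Cyp4a, Gst, Scd, Saa, Orm, Tex19 and globin families carry that limit. Of the 135 named genes, 17 overlap the span of another annotated gene, among them Pltp with Ctsa, Tm7sf2 with Vps51, Slc31a1 with Fkbp15, Cdc20 with Elovl1 and Aurka with Cstf1.

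Library totals ranged from 16535938 to 28329751 counts. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 13379 genes and set aside 11153, of which 5810 had no count in any library. All 12 libraries entered 1 edgeR quasi-likelihood fit (edgeR 4.0.16, R 4.3.3) with group means and TMM scaling, and each of the 3 comparisons was a contrast of that fit. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes carry the standard error (SE) of the log2 value, and levels are CPM (counts per 1e6 counts) on TMM-scaled library sizes, as mean and SD over 4 libraries. The titles carry animal numbers, and nothing states whether equal numbers share a litter or a day. The p-values therefore measure the spread between these 12 libraries, which were taken as 12 separate animals.

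Where all 4 libraries of a group were at 0, the fold is a lower bound against 3 counts over that group's libraries. Where a group held 1 to 3 counts, the ratio of levels is given with its exact Clopper-Pearson 95% interval. Such bounds and intervals cover counting error only. A comparison of 4 with 4 values by exact permutation cannot give a two-sided p under 0.0286.

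Before the data were examined, 29 gene lists were fixed from textbook knowledge. The pathway lists were LXR targets, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, fatty acid oxidation and PPAR alpha targets, copper and metal handling, NRF2 targets, cytochrome P450s of drug metabolism, cytokines with chemokines and adhesion, acute phase, cell cycle, p53 targets, endoplasmic reticulum and amino acid stress, oxidative phosphorylation and nuclear receptors. The cell type lists were extracellular matrix and stellate cell, macrophage and Kupffer cell, neutrophil, T and NK cell, B and plasma cell, cholangiocyte and ductular, sinusoidal endothelial, erythroid, adipocyte with pancreas and muscle, and hepatocyte function. The circadian clock, female-biased, male-biased and sex chromosome lists served as checks of time of day and sex. Whole liver holds these cell types, apart from the adipocyte, pancreas and muscle list, which stands for other tissues and had 3 of 14 members past the filter. Each list was tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the 29 lists), with camera at an estimated correlation, and with fry, which asks only whether a list's genes move one way on balance. Members are counted over all genes tested and adjusted over the list alone.

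The named genes follow a rule fixed at the same time. It takes Atp7b, and the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM in the higher group, no overlap between the groups and no predicted or clone name. It adds the 2 members with the smallest adjusted p from each list that was called or had at least 3 called members, and the 3 smallest for the LXR, cholesterol, copper and matrix lists. It also takes the 5 genes with opposite calls in KO vs Het and KO_drug vs KO that have the largest product of changes. Of the genes that this rule takes from lists, 1 is not reported here. The opposite calls were set beside the overlap of independent lists, the signs and covariance of the changes beside 20 simulations in which the comparisons share the KO libraries, and both beside fits with the KO libraries divided 2 and 2. Genes within 10 Mb of Atp7b were compared with all others by Fisher's exact test.

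The fit was tested on simulated data of the same size, with 50 changed genes at each of 4 sizes. For KO vs Het it recovered 52% of changes of 1 on the log2 scale, 78% at 1.5, 86% at 2 and 94% at 3, and 3.13% of its calls were false. For KO_drug vs KO the shares were 50%, 86%, 80% and 98% with 4.27% false, and for KO_drug vs Het 58%, 68%, 88% and 96% with 7.74% false. These simulations called 160 to 168 genes, far fewer than the data, so their recovered and false shares need not carry over.

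Alternatives were the 2 compared groups alone, a term for equal animal numbers, leaving out each library in turn, DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, limma with sample weights, and a sex term. That term set a library as female where its Xist counts exceeded its Ddx3y counts, which held for KO 5 alone and not for KO 6. After the data had been seen, 4 were added: KO 2 and KO 4 as the KO group, total-count scaling, leaving out the 100 most abundant genes, and limma with trend on log2 of the deposited FPKM plus 1. In groups of 4 libraries, a value was picked out when its gap to the nearest other, over the group's range, exceeded Dixon's critical value of 0.829.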

Results

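The data are 12 liver libraries from mice of 20 wk, with 4 Het controls, 4 Atp7b-/- mice (KO) and 4 Atp7b-/- mice fed an LXR agonist (KO_drug). Atp7b encodes the copper-transporting ATPase whose loss causes Wilson disease. In units of 1e6 counts, library totals were 22.8 ± 2.31 in Het (mean ± SD, n = 4; range 19.7 to 25.1), 23.3 ± 5.71 in KO (16.5 to 28.3) and 19.7 ± 0.594 in KO_drug (18.8 to 20.2). The mean number of genes with a count was 14026 in Het, 16188 in KO and 14358 in KO_drug. Pairs of libraries within a group correlated across genes at 0.952 to 0.979, and the mean over pairs was 0.891 between Het and KO, 0.920 between Het and KO_drug and 0.933 between KO and KO_drug. The first principal component held 51.0% of the variance and placed the KO libraries at 60.9 to 73.7, the Het libraries at -82.8 to -69.0 and the KO_drug libraries at -3.71 to 41.2, with KO_drug 1 nearest to KO.

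The major urinary proteins, abundant secreted products of male mouse liver, took 13.5 ± 2.08% of all counts in Het, 1.78 ± 0.669% in KO and 3.78 ± 1.22% in KO_drug (n = 4 each). The 100 most abundant genes took 48.2%, 35.4% and 42.2%. TMM scaling sets the median change of all genes at 0.02 in KO vs Het, while total-count scaling puts it at 0.54 in KO vs Het, -0.36 in KO_drug vs KO and 0.18 in KO_drug vs Het on the log2 scale. All changes in the text are relative to the TMM median.

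Xist, the RNA that coats the inactive X chromosome of female cells, stood at 81.8 CPM in KO 5 and 17.8 CPM in KO 6, and at 0.425 CPM or less in the other 10 libraries. Ddx3y, a gene of the Y chromosome, stood at 0.379 CPM in KO 5, 64.4 CPM in KO 6 and between 79.5 and 111 CPM elsewhere. The labels give no sex. Counts are therefore also given with KO 2 and KO 4 as the only KO libraries.

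**Figure D1:**
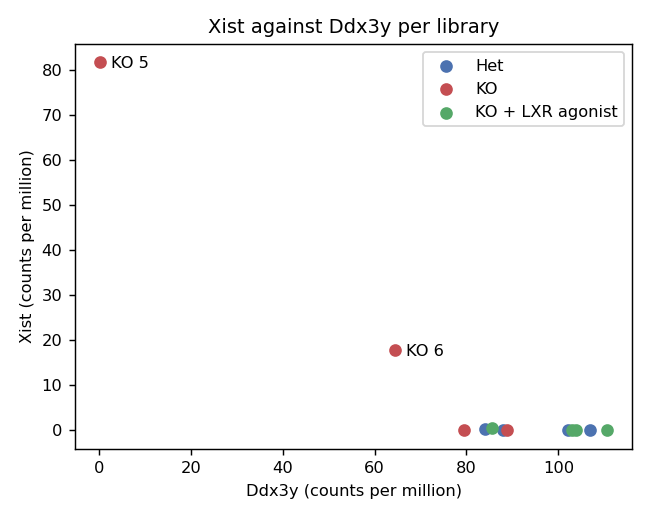
Each point is a library, with the level of Ddx3y on the x axis and of Xist on the y axis, both in CPM, and colours give the group. KO 5 lies at 81.8 CPM of Xist with 0.379 CPM of Ddx3y, and KO 6 at 17.8 and 64.4 CPM, while the other 10 libraries lie at 0.425 CPM of Xist or less.

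The targeted gene, Atp7b (gene number 11979, chromosome 8, 21992783 to 22060074, mm10), was lower in both knockout groups. Its level was 12.9 ± 2.62 CPM in Het, 2.09 ± 0.476 CPM in KO and 2.22 ± 1.11 CPM in KO_drug (mean ± SD, n = 4 each). It was 6.12-fold lower in KO than in Het (log2 -2.61, SE 0.32, adjusted p = 5.3e-05) and 5.77-fold lower in KO_drug than in Het (log2 -2.53, SE 0.32, adjusted p = 9.7e-05). In both comparisons all 4 knockout libraries lay below all 4 Het libraries, which is the exact two-sided permutation p of 0.0286 that 4 against 4 can reach at best. KO_drug and KO differed by 0.09 (SE 0.32, adjusted p = 0.878; exact permutation p = 0.943). Transcript remained at 36 to 93 counts per KO library. Since the strain is mixed, genes linked to Atp7b were compared with the rest: 39 of 89 tested genes within 10 Mb (43.8%) were called in KO vs Het against 40.7% elsewhere (odds ratio 1.14, 95% interval 0.727 to 1.77, two-sided Fisher's exact p = 0.589). For KO_drug vs KO the shares were 16.9% and 19.9% (odds ratio 0.818, 95% interval 0.435 to 1.44, two-sided Fisher's exact p = 0.593).

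**Figure D2:**
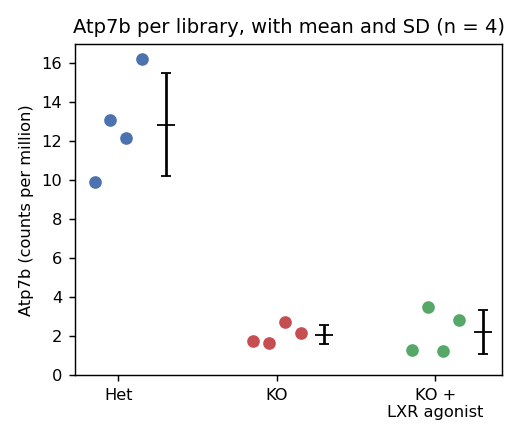
Atp7b in CPM is on the y axis, with 1 point per library, the group on the x axis, and the mean with SD bars beside each group (n = 4). The Het libraries sit between 9.90 and 16.2 CPM and the 8 knockout libraries between 1.27 and 3.49 CPM.

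KO vs Het asks what the loss of Atp7b changes in liver RNA. Genes of cell division and targets of p53, the damage-response transcription factor, were higher in KO: 21 of 27 cell cycle genes and 14 of 14 p53 targets rose. Cdc20, an activator of the complex that drives anaphase, went from 0.647 ± 0.297 to 24.1 ± 5.94 CPM (36.9-fold), and Eda2r, a receptor of the TNF receptor family and a p53 target, from 0.649 ± 0.0551 to 41.3 ± 9.38 CPM (63.1-fold; mean ± SD, n = 4 per group). Markers of macrophages and of T and NK cells rose in 18 of 20 and 8 of 9 measured members. Bile acid genes and respiratory chain genes fell, with 15 of 19 and 23 of 25 members called lower, and Slc10a1, the sodium-dependent bile acid importer of hepatocytes, was 5.46-fold lower (93.5 ± 35.7 against 510 ± 112 CPM). Mt1, a metallothionein that binds copper and zinc, rose 23.3-fold to 1988 ± 476 CPM, and without Het 4, the library with the highest Het level, its log2 change was 5.88 in place of 4.54 (SE 0.74).

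Of 13379 genes, 5448 were called in KO vs Het, 3077 higher and 2371 lower, and 2117 of the higher and 539 of the lower genes changed at least 2-fold. With KO 2 and KO 4 alone, 4842 genes were called. The groups did not overlap for 5257 genes (39.3%), against 2.86% by chance. Under total-count scaling 7369 genes were called, 93.8% of them higher. Of the 5448 genes called under TMM scaling, 665 had the opposite sign there, whether called there or not.

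Several of the largest rises were of genes without a count in Het. Spink1, a secreted trypsin inhibitor, stood at 31.4 ± 5.60 CPM in KO (at least 807-fold higher), Mgst2, a microsomal glutathione transferase, at 22.0 ± 5.68 CPM (at least 565-fold), Myo7b, a myosin of the brush border, at 21.5 ± 1.83 CPM (at least 554-fold) and Got1l1 at 20.4 ± 5.08 CPM (at least 524-fold). Got1l1 lies within 10 Mb of Atp7b (chromosome 8, 27197459 to 27223845). For this gene a linked strain allele cannot be told apart from the loss of Atp7b. Tex19.1, a gene of germ cells and placenta, was at least 1356-fold higher (52.7 ± 53.4 CPM), or at least 724-fold without KO 5. Wfdc12 was at least 1016-fold higher (39.5 ± 30.5 CPM), or at least 630.4-fold without KO 6. The largest falls were of hepatocyte genes. Cyp2c54 (log2 -4.45, SE 0.34) and Cyp2c29 (-4.33, SE 0.46, or -5.31 with KO 2 and KO 4 alone) encode cytochrome P450s, Sult2a8 (-4.25, SE 0.34) a sulfotransferase and Ces4a (-4.20, SE 0.64) a carboxylesterase. Hsd3b5, a steroid dehydrogenase of male liver, fell by 4.36 (SE 1.10), or by 5.05 without KO 2. Its adjusted p was 0.0527 with KO 2 and KO 4 alone. Mup11 fell by 9.24 (SE 1.76), but its Het libraries ranged from 21.4 to 7053 CPM. Its change was -8.23 without Het 2 and -10.16 without KO 2, and limma with sample weights gave an adjusted p of 0.0668.

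The cell cycle list rose with 21 of 27 measured members called higher and none lower (23 adjusted over the list alone; camera adjusted p = 2.3e-14, and adjusted p = 0.290 with an estimated correlation). Aurka, a mitotic kinase, was 10.8-fold higher (log2 3.44, SE 0.21). All 14 p53 targets rose, over all genes and adjusted over the list alone (adjusted p = 2.1e-14, and 0.222 with an estimated correlation), among them Phlda3, an inhibitor of Akt signalling, 58.5-fold higher (log2 5.87, SE 0.37). Of 20 NRF2 targets, genes of the response to oxidants, 11 rose and 1 fell (13 and 3 adjusted over the list alone; adjusted p = 0.000522, and 0.290 with an estimated correlation). Gsta1, a glutathione transferase, was 24.1-fold higher (log2 4.59, SE 0.31) and Srxn1, which repairs oxidized peroxiredoxins, 3.17-fold higher (1.66, SE 0.17). Of 18 copper and metal genes 4 rose and 7 fell (6 and 8 adjusted over the list alone, but 10 and 2 under total-count scaling), and the list was not called (adjusted p = 0.840), with a median of 0.26 and a test sign that was negative. Beside Mt1, Slc31a1, the plasma membrane copper importer, was 2.08-fold lower (log2 -1.06, SE 0.18), and Ccs, the copper chaperone of superoxide dismutase, 1.55-fold lower (-0.63, SE 0.11), which total-count scaling did not call (adjusted p = 0.509).

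Markers of immune cells were higher in KO, and more so in KO 2 and KO 4 than in KO 5 and KO 6, the libraries with Xist. The mean log2 CPM of the macrophage list was 5.753 and 5.654 against 4.526 and 4.684 (at most 3.370 in Het), of cytokines 4.690 and 4.701 against 3.091 and 3.164, and of T and NK markers 1.368 and 1.319 against 0.03792 and -0.02112. The macrophage and Kupffer cell list had 18 of 20 members called higher, also adjusted over the list alone (adjusted p = 5.5e-07, and 0.429 with an estimated correlation). Cd68, a lysosomal protein of macrophages, was 2.82-fold higher (28.9 ± 8.09 against 10.3 ± 1.72 CPM) and C1qc, a chain of complement C1q, 3.18-fold. The cytokine, chemokine and adhesion list rose in 12 of 15 members (12 adjusted over the list alone; adjusted p = 0.000132, and 0.429 with an estimated correlation). Il1b, an inflammatory cytokine, was 6.11-fold and Icam1, an adhesion molecule of leukocyte binding, 5.45-fold higher. T and NK markers rose in 8 of 9 members (adjusted p = 0.0131) and neutrophil markers in 6 of 7 (adjusted p = 0.0151), with the same numbers adjusted over the list alone. With an estimated correlation their adjusted p-values were 0.429 and 0.450. S100a8, a calcium-binding protein of neutrophils, rose by 3.33 (SE 0.65) on the log2 scale, or 2.45 without KO 4. Mmp8, the neutrophil collagenase, had 2 counts in Het and 220 in KO, a ratio of levels of 74.8 (95% interval 20.5 to 621). The log2 change of Mmp8, 6.11 (SE 0.99), was 5.37 without KO 4. Without Het 2 it was 8.62, but Het then stood at 0, so that value is not a measured size. Gzmb and Cd3d had 5 counts each in Het, and their levels in KO were 1.62 ± 0.792 and 1.52 ± 0.840 CPM. The log2 change of Gzmb was 4.53 (SE 1.04), or 8.19 without Het 4, and that of Cd3d 4.43 (SE 1.07), or 8.10 without Het 2. Without those libraries Het stood at 0 for the gene, so 8.19 and 8.10 are not measured sizes either. Of 4 B and plasma cell markers 2 rose (adjusted p = 0.235 for the list), and of 21 acute phase genes 7 rose and 2 fell (13 and 0 under total-count scaling; adjusted p = 0.308). Among the latter, Lcn2, an iron-scavenging protein, rose by 6.93 (SE 1.37), or 8.49 without Het 4, with a spread of 1144 ± 1099 CPM in KO.

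Matrix and duct markers were higher as well. The extracellular matrix and stellate cell list rose in 13 of 23 members (13 adjusted over the list alone; adjusted p = 0.00497, and 0.452 with an estimated correlation). The mean log2 CPM of the list was 4.070 and 4.399 in KO 2 and KO 4 against 3.138 and 3.367 in KO 5 and KO 6 (at most 2.832 in Het). Col1a2, a chain of collagen I, was 3.36-fold higher (log2 1.75, SE 0.34), Vim, an intermediate filament of mesenchymal cells, 3.45-fold (1.79, SE 0.35) and Loxl2, a collagen-crosslinking oxidase, 3.45-fold (1.79, SE 0.32). The cholangiocyte and ductular list had 8 of 14 members higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00443, and 0.377 with an estimated correlation). Krt23, a keratin, was 11.0-fold and Spp1, osteopontin, 4.23-fold higher. Sinusoidal endothelial markers had 3 of 11 members higher, 2 adjusted over the list alone (adjusted p = 0.853 for the list), Tek by 0.85 (SE 0.17) and Pecam1 by 0.56 (SE 0.15), with a list median of -0.13 that turned to 0.41 under total-count scaling (5 higher) and 0.42 on FPKM. Erythroid markers had 1 of 7 lower and the adipocyte, pancreas and muscle list 1 of 3, and neither list was called (adjusted p = 0.854 and 0.462).

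Hepatocyte pathways were lower. The oxidative phosphorylation list fell in 23 of 25 members (24 adjusted over the list alone; adjusted p = 4.7e-09, and 0.303 with an estimated correlation). Cyc1, cytochrome c1, was 2.05-fold lower (log2 -1.04, SE 0.13) and Atp5c1, a subunit of ATP synthase, 1.95-fold lower (-0.96, SE 0.13). Bile acid synthesis and transport fell in 15 of 19 members, also adjusted over the list alone (adjusted p = 8.2e-06, and 0.290 with an estimated correlation). Abcb11, the canalicular bile salt exporter, was 2.61-fold lower (-1.38, SE 0.19). Cholesterol synthesis and uptake fell in 12 of 25 members (15 adjusted over the list alone; adjusted p = 2.9e-05, and 0.450 with an estimated correlation). Sc5d and Tm7sf2, enzymes of the late sterol steps, fell by 1.94 (SE 0.31) and 1.43 (SE 0.18), and Insig1, a sterol sensor partner, fell by 1.34 (SE 0.20). Hepatocyte function genes fell in 12 of 22 members (13 adjusted over the list alone; adjusted p = 6.0e-05, and 0.429 with an estimated correlation). Hnf4a, a master regulator of hepatocytes, was 1.91-fold and Glul, glutamine synthetase, 2.65-fold lower. Nuclear receptors fell in 9 of 16 members (9 adjusted over the list alone; adjusted p = 0.00443, and 0.222 with an estimated correlation). Cytochrome P450s had 9 of 17 lower and 4 higher (likewise adjusted over the list alone; adjusted p = 0.00338, and 0.429 with an estimated correlation), with Cyp2c37 9.48-fold lower. Under total-count scaling the median of the oxidative phosphorylation list moved from -0.63 to -0.11 with 4 members called lower, of the nuclear receptors from -0.54 to -0.02 with 1 lower and 3 higher, of the P450s from -0.63 to -0.08 with 6 lower and 5 higher, and of the hepatocyte list from -0.81 to -0.27 with 5 lower and 1 higher. Bile acid genes then had 9 called lower with 3 higher, and cholesterol genes 6 lower with 1 higher.

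Lipid genes went both ways under TMM scaling. Of 19 LXR targets 5 rose and 4 fell (8 and 1 under total-count scaling), and the list was not called (adjusted p = 0.854; median 0.01 with a test sign that was negative). Lpl, lipoprotein lipase, was 5.03-fold higher (log2 2.33, SE 0.31), Pltp, the phospholipid transfer protein, 3.30-fold (1.72, SE 0.26) and Smpdl3a 1.55-fold (0.64, SE 0.11). Fatty acid and triglyceride synthesis had 7 of 22 members lower and 3 higher (8 and 3 adjusted over the list alone; adjusted p = 0.0399, and 0.450 with an estimated correlation), and its median of -0.50 turned to 0.01 under total-count scaling (5 higher and 2 lower) and 0.07 on FPKM. That list was not called without Het 4 (adjusted p = 0.0799), KO 4 (0.0858) or KO 5 (0.0665). The fatty acid oxidation list was not called (adjusted p = 0.235; 2 of 23 higher and 6 lower), and its median of -0.02 turned to 0.50 under total-count scaling (8 higher and 1 lower) and 0.35 on FPKM. In it, Pdk4, a brake on pyruvate oxidation, was 6.31-fold higher and Fabp1, the liver fatty acid binding protein, 4.61-fold lower. Of the stress list of the endoplasmic reticulum and amino acids 7 of 14 members fell and 2 rose (3 and 4 under total-count scaling; adjusted p = 0.105), the 2 being Asns, asparagine synthetase (log2 1.95, SE 0.23), and Atf3, a stress-induced transcription factor (2.70, SE 0.39).

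Among the checks, the female-biased and male-biased lists were called, and the clock and sex chromosome lists were not. Of 8 female-biased genes 3 rose, also adjusted over the list alone (6 under total-count scaling; adjusted p = 0.0250, and 0.452 with an estimated correlation), and of 11 male-biased genes 8 fell (9 adjusted over the list alone; adjusted p = 0.000491, and 0.429 with an estimated correlation). The female-biased list was not called without KO 5 (adjusted p = 0.0665), without KO 6 (0.0532) or with KO 2 and KO 4 alone (0.201), the libraries with Xist being KO 5 and KO 6. Cyp2a4, a cytochrome P450 of female liver, rose 38.4-fold to 1251 ± 554 CPM (log2 5.26, or 4.57 with KO 2 and KO 4 alone). Prom1, which is also on the cholangiocyte and ductular list, rose by 5.20 (SE 0.95), or 4.61 without KO 5 and 7.08 without Het 4. Slco1a1, an organic anion transporter of male liver, fell 16.2-fold and Nudt7, a peroxisomal hydrolase, 5.93-fold. Of 16 clock genes 4 fell (4 adjusted over the list alone; adjusted p = 0.126 for the list), Cry1 by 1.34 (SE 0.32) and Hlf by 1.09 (SE 0.27), and the list median of -0.46 turned to 0.05 under total-count scaling (1 higher and 1 lower), where Hlf was not called (adjusted p = 0.0867). None of the 4 measured sex chromosome genes was called in edgeR (adjusted p = 0.284 for the list).

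**Figure D3:**
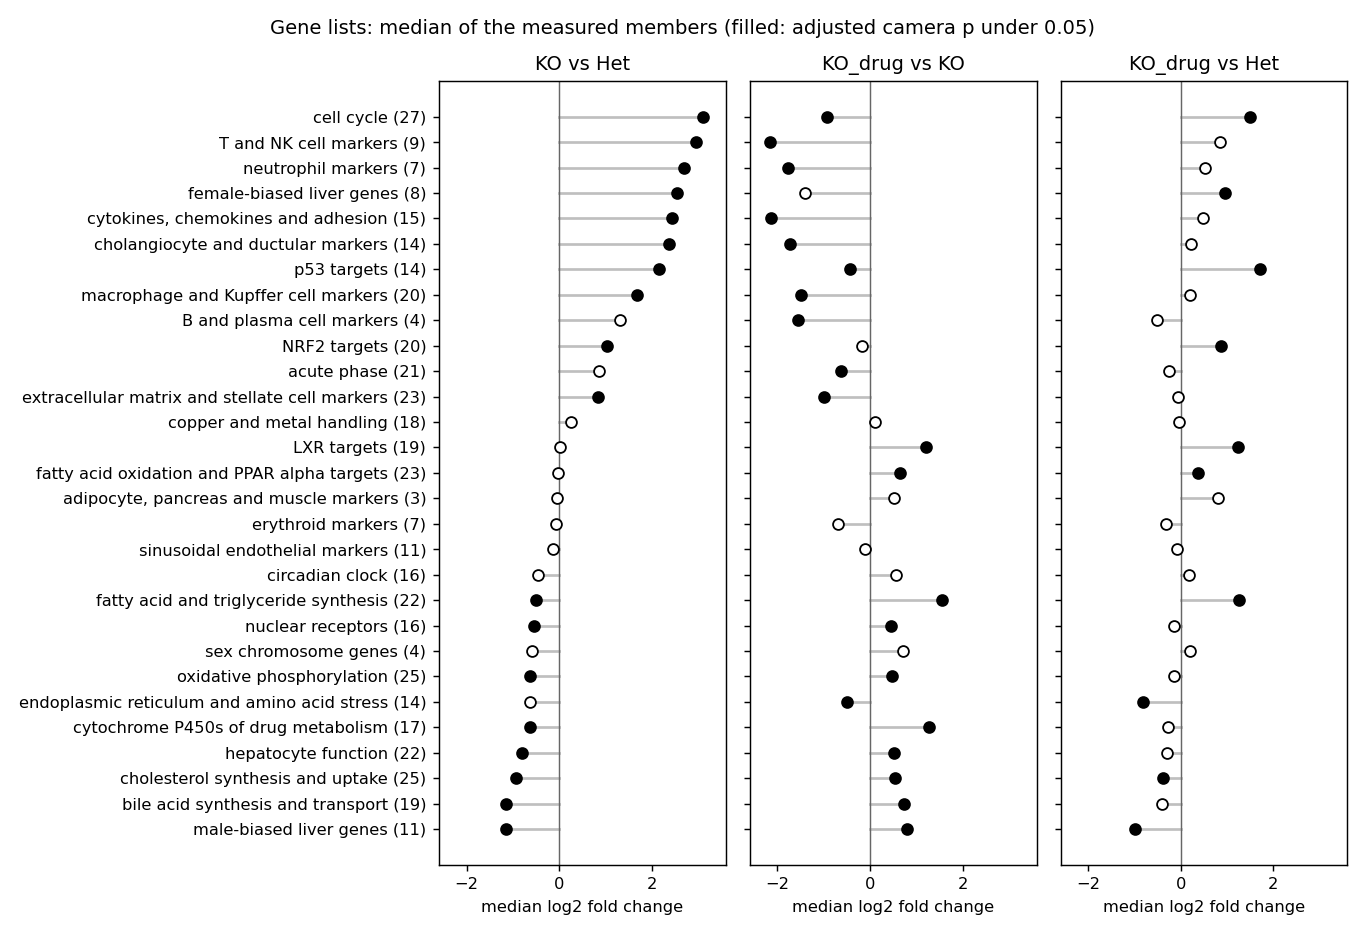
Each row is a gene list with the number of measured members in brackets, and the x axis is the median log2 fold change of its members under TMM scaling in 3 comparisons, filled where the adjusted camera p is under 0.05. In KO vs Het the cell cycle list sits at 3.10 and the bile acid list at -1.14, and in KO_drug vs KO fatty acid synthesis sits at 1.56 and cytokines at -2.13; under total-count scaling the signs of fatty acid synthesis, fatty acid oxidation, endothelial, erythroid, clock and adipocyte medians turn in KO vs Het, of copper genes in KO_drug vs KO, and of copper, matrix, endothelial, respiratory chain and nuclear receptor medians in KO_drug vs Het.

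KO_drug vs KO asks what the LXR agonist changes in the knockout liver. LXR targets and genes of fatty acid synthesis rose, with 12 of 19 and 17 of 22 members called higher and none lower. Scd1, the desaturase that makes oleate, went from 2678 ± 1249 to 60266 ± 11935 CPM (22.5-fold), and Fasn, fatty acid synthase, from 158 ± 33.9 to 1138 ± 201 CPM (7.22-fold; mean ± SD, n = 4 per group). Markers of macrophages and cytokines fell, with 15 of 20 and 12 of 15 members called lower, and Cd68 was 3.08-fold lower (9.39 ± 2.48 against 28.9 ± 8.09 CPM). Respiratory chain genes and P450s rose in 17 of 25 and 10 of 17 members. Cell cycle genes and p53 targets fell in 9 of 27 and 4 of 14 members.

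In this comparison 2654 genes were called, 1177 higher and 1477 lower, with 297 and 1019 of them changed at least 2-fold, and 2661 with KO 2 and KO 4 as the KO group. The count was 1633 without KO 4 and 1632 without KO_drug 3, and 4255 under total-count scaling, where 8.32% of the calls were higher.

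Inmt, a methyltransferase of indole amines, showed the largest rise, from 11.0 ± 1.46 to 840.5 ± 359 CPM (log2 6.25, SE 0.36). Cyp2c29 rose 22.0-fold (4.46, SE 0.46, or 5.42 with KO 2 and KO 4 alone), Scd4 19.2-fold (4.26, SE 0.83) and Fabp5, a fatty acid binding protein, 13.4-fold (3.74, SE 0.37). Slc2a4, the insulin-responsive glucose transporter, rose by 5.23 (SE 0.93) with 13 counts in KO, or 6.03 without KO 2, and limma with sample weights gave an adjusted p of 0.0728. Genes without a count in KO_drug made up the largest falls. Ogdhl was at least 70.9-fold lower (2.80 ± 2.70 CPM in KO), or at least 40.3-fold without KO 5. Duox2, a hydrogen peroxide-producing oxidase, was at least 40.2-fold lower, Asb11 at least 32.8-fold, Rab44 at least 27.6-fold, Cdh17, a cadherin of the intestine, at least 26.0-fold and Kif5c at least 25.5-fold, all from means of 1.01 to 1.59 CPM in KO.

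The LXR target list had the same 12 of 19 members higher adjusted over the list alone (camera adjusted p = 6.8e-14, and 0.0171 with an estimated correlation), and fatty acid and triglyceride synthesis 20 of 22 (adjusted p = 4.4e-27, and 0.00870 with an estimated correlation). These were the 2 lists called with an estimated correlation. Acacb, an acetyl-CoA carboxylase, was 7.45-fold higher (log2 2.90, SE 0.27) and Mlxipl, the glucose-sensing transcription factor ChREBP, 4.20-fold (2.07, SE 0.27). Fatty acid oxidation and PPAR alpha targets rose in 11 of 23 members (14 adjusted over the list alone, but 5 under total-count scaling; adjusted p = 6.0e-08, and 0.196 with an estimated correlation). Acaa1a, a peroxisomal thiolase, was 2.11-fold higher. Cholesterol synthesis and uptake rose in 4 of 25 members (3 adjusted over the list alone; adjusted p = 0.00101, and 0.464 with an estimated correlation), Pmvk 3.11-fold, Insig1 2.26-fold and Tm7sf2 2.15-fold, and the list was not called without KO_drug 2 (adjusted p = 0.201). Bile acid genes rose in 9 of 19 members (10 adjusted over the list alone; adjusted p = 2.6e-06, and 0.196 with an estimated correlation), with Cyp27a1, sterol 27-hydroxylase, 2.27-fold and Abcb11 1.96-fold higher.

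Of 17 cytochrome P450s 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 3.0e-11, and 0.119 with an estimated correlation), with Cyp2c54 8.62-fold and Cyp2c37 4.39-fold higher. Oxidative phosphorylation rose in 17 of 25 members (23 adjusted over the list alone; adjusted p = 2.1e-10, and 0.196 with an estimated correlation), with Sdhb, a subunit of succinate dehydrogenase, 1.82-fold higher (log2 0.86, SE 0.14). Hepatocyte function genes rose in 5 of 22 members (7 adjusted over the list alone; adjusted p = 0.000630, and 0.365 with an estimated correlation), with Hpd, an enzyme of tyrosine breakdown, 2.57-fold and Arg1, arginase, 1.78-fold higher. Nuclear receptors rose in 5 of 16 members (6 adjusted over the list alone; adjusted p = 0.00512, and 0.119 with an estimated correlation). Under total-count scaling the oxidative phosphorylation median moved from 0.48 to 0.13 with 1 member called, that of nuclear receptors from 0.44 to 0.10 with 0 called in edgeR, and that of hepatocyte genes from 0.51 to 0.17 with 2 higher and 2 lower. Male-biased genes rose in 3 of 11 members, also adjusted over the list alone (adjusted p = 0.0123, and 0.406 with an estimated correlation), with Cyp4a12b 3.00-fold and Cyp4a12a 2.62-fold higher, and the list was not called without KO_drug 2 (adjusted p = 0.130) or with KO 2 and KO 4 alone (0.0727).

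Immune and matrix markers fell. The macrophage list had 18 of 20 members lower adjusted over the list alone (adjusted p = 1.3e-12, and 0.196 with an estimated correlation), with Csf1r, the receptor for the growth factor of macrophages, 2.77-fold lower. Cytokines, chemokines and adhesion had 14 of 15 lower adjusted over the list alone (adjusted p = 4.7e-08, and 0.196 with an estimated correlation), Icam1 4.94-fold and Il1b 4.39-fold lower. T and NK markers fell in 4 of 9 members (7 adjusted over the list alone; adjusted p = 0.000879), and B and plasma cell markers in 3 of 4 (4 adjusted over the list alone; adjusted p = 0.00281), each with an adjusted p of 0.196 with an estimated correlation. Cd22 and Cd79b, surface proteins of B cells, were 2.91-fold and 4.70-fold lower, and Cd3g, a chain of the T cell receptor complex, fell by 3.65 (SE 0.82) with 7 counts in KO_drug, or by 4.39 without KO_drug 2. Neutrophil markers fell in 3 of 7 members (6 adjusted over the list alone, and 6 under total-count scaling; adjusted p = 0.0151, and 0.399 with an estimated correlation), and the list was not called without KO 4 (adjusted p = 0.0659). Acute phase genes fell in 4 of 21 members (5 adjusted over the list alone, and 13 under total-count scaling; adjusted p = 0.00357, and 0.399 with an estimated correlation), with Orm2, an acid glycoprotein, 13.1-fold lower. The log2 change of Orm2, -3.714, was -4.495 with KO 2 and KO 4 alone. In KO_drug 1 the mean log2 CPM lay within the KO range for neutrophil markers (1.34, against 0.9569 to 3.287) and for acute phase genes (8.467, against 8.192 to 9.632). KO_drug 2, KO_drug 3 and KO_drug 4 lay lower, at -0.3201, -0.5041 and 0.3814 and at 7.409, 7.524 and 7.789. Saa3, a serum amyloid, changed by -4.71 (SE 1.10), or -4.09 without KO 4 and -5.46 without KO_drug 1, and limma with sample weights did not call it (adjusted p = 0.0855).

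The matrix and stellate list fell in 11 of 23 members (17 adjusted over the list alone, and 17 under total-count scaling; adjusted p = 1.3e-07, and 0.211 with an estimated correlation). Col1a2 was 3.51-fold, Col5a2 3.75-fold and Lum, a small proteoglycan of matrix, 2.70-fold lower. Duct markers fell in 5 of 14 members with 1 higher (7 and 1 adjusted over the list alone; adjusted p = 0.00565, and 0.218 with an estimated correlation), with Spp1 3.77-fold lower. Cell cycle genes fell in 9 of 27 members with 1 higher (11 and 1 adjusted over the list alone, and 14 and 0 under total-count scaling; adjusted p = 5.2e-05, and 0.377 with an estimated correlation), with Mcm4, a subunit of the replicative helicase, 2.92-fold lower. The mean log2 CPM of the list in KO_drug 1, 3.319, lay within the KO range of 2.913 to 3.707, while KO_drug 2, KO_drug 3 and KO_drug 4 lay at 1.914, 1.698 and 2.093. With KO 2 and KO 4 alone the list was not called (adjusted p = 0.0727). p53 targets fell in 4 of 14 members (6 adjusted over the list alone, and 7 under total-count scaling; adjusted p = 0.00614, and 0.399 with an estimated correlation), with Phlda3 2.76-fold and Ddit4l 3.53-fold lower, and without KO_drug 2 the list was not called (adjusted p = 0.0693). Of the stress list 3 of 14 members fell, also adjusted over the list alone (8 under total-count scaling; adjusted p = 0.0244, and 0.313 with an estimated correlation), among them Sdf2l1, an endoplasmic reticulum chaperone partner, 3.54-fold, and the list was not called without KO 5 (adjusted p = 0.104) or with KO 2 and KO 4 alone (0.153). NRF2 targets had 1 of 20 members higher and 1 lower (0 and 8 under total-count scaling; adjusted p = 0.445), and copper genes 3 of 18 higher and 2 lower (1 and 4 under total-count scaling; adjusted p = 0.288), their median of 0.12 turning to -0.22 under total-count scaling. Among the copper genes Sco2, a copper carrier for cytochrome c oxidase, was 2.05-fold higher and Steap4, a metalloreductase, 3.25-fold lower. Mt1 was not called (2795 ± 502 CPM in KO_drug and 1988 ± 476 CPM in KO).

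**Figure D4:**
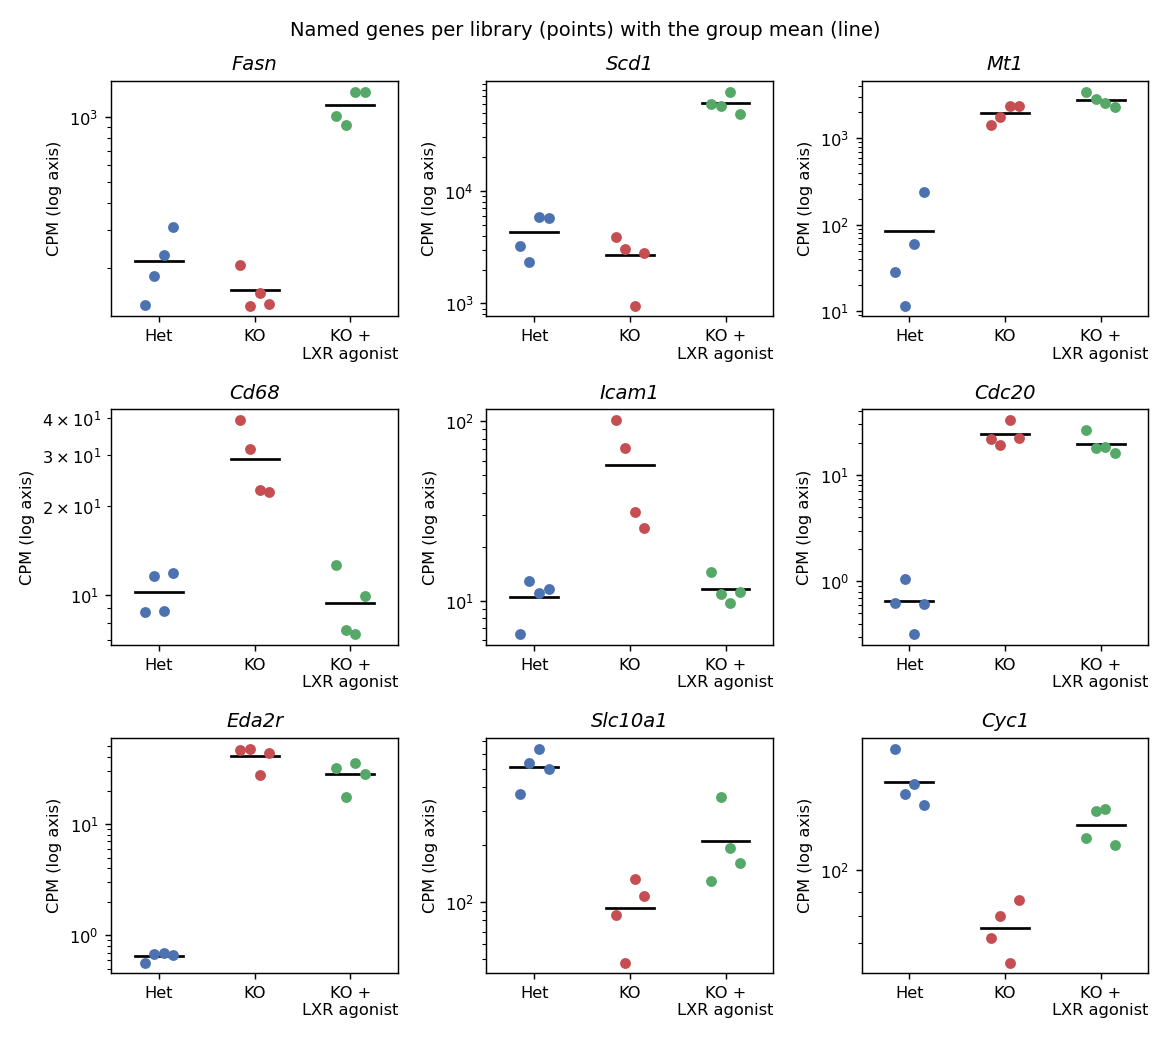
The y axes are CPM on a log axis, with 1 point per library, lines at the group means (n = 4) and the 3 groups on the x axis. Fasn and Scd1 lie highest in KO_drug (means of 1138 and 60266 CPM), Cd68 and Icam1 lie highest in KO (28.9 and 57.2 CPM), and Cdc20 and Eda2r lie above Het (0.647 and 0.649 CPM) in both knockout groups.

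The 2 comparisons were then read together, to ask how far changes of the knockout were opposed in mice fed the agonist. No Het mice were fed the agonist. An opposite call can therefore not be told apart from a change that the agonist makes whatever the genotype. Of the 3077 genes higher in KO vs Het, 1137 (37.0%) were called lower in KO_drug vs KO, and of the 2371 lower genes 725 (30.6%) were called higher. That makes 1862 opposite calls, against 548 expected of independent lists, while 77 genes were called in the same direction. Called or not in KO_drug vs KO, 84.5% of the genes called in KO vs Het changed with opposite sign there, against 58.1% on average in 20 simulations in which the agonist changes nothing. All 12 called cytokine, chemokine and adhesion genes, 15 of 18 macrophage genes, 17 of 23 respiratory chain genes and 9 of 13 matrix genes had opposite calls. Those of the respiratory chain depend on the scaling, since under total-count scaling 4 of its genes were called lower in KO vs Het and 1 higher in KO_drug vs KO. The share was 7 of 21 for the cell cycle, 4 of 14 for p53 targets, 1 of 12 for NRF2 targets and 0 of 9 for the stress list. Ogdhl, Duox2, Asb11, Cdh17 and Pkp1, a desmosomal plakophilin, had the largest products of the 2 changes: all 5 were at 0 in Het, 4 were at 0 in KO_drug, and Pkp1 went from 3.26 ± 1.65 CPM in KO to 0.106 ± 0.130 CPM. The change of Pkp1 in KO_drug vs KO was -4.88 (SE 0.81), or -5.81 without KO_drug 4.

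The KO libraries enter both comparisons with opposite sign, so part of any negative relation is built in. The covariance of the changes was -0.715 across genes, against -0.0629 on average in simulations without any effect and -0.0598 with the agonist changing nothing. With the KO libraries divided 2 and 2, so that the comparisons share none, opposite calls numbered 607 to 1102 and the covariance lay between -0.678 and -0.507. The number of opposite calls was 1142 without KO 4, 1218 without KO_drug 3 and 1971 with KO 2 and KO 4 alone. Of the genes called in KO vs Het, 41.5% of the higher and 33.8% of the lower genes were still called in the same direction in KO_drug vs Het. A further 715 genes were called in KO_drug vs KO and not in KO vs Het, 396 higher and 319 lower.

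KO_drug vs Het asks what distinguishes the agonist-fed knockout liver from the control, with genotype and agonist differing together. Genes of fatty acid synthesis and LXR targets were higher, in 15 of 22 and 13 of 19 members with none lower. Scd2, a desaturase, was 21.0-fold higher (191 ± 119 against 9.06 ± 1.18 CPM) and Lpl 16.9-fold (365 ± 117 against 21.6 ± 8.66 CPM; mean ± SD, n = 4 per group). Targets of p53 and cell cycle genes were higher in 12 of 14 and 13 of 27 members, Eda2r by 43.2-fold (28.3 ± 7.70 CPM) and Cdc20 by 30.1-fold (19.7 ± 4.72 CPM). In edgeR 0 of 15 cytokine and 0 of 25 respiratory chain genes were called, and 2 of 20 macrophage genes were called higher. Mt1 was 32.7-fold higher (2795 ± 502 CPM; log2 5.03, SE 0.76, or 6.37 without Het 4).

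Of 13379 genes, 2865 were called in KO_drug vs Het, 1735 higher and 1130 lower, and 1028 and 345 of them changed at least 2-fold. With KO 2 and KO 4 alone in the shared fit, 2826 were called. Under total-count scaling 2932 were called, 82.98% of them higher.

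Several of the largest rises were again of genes without a count in Het. Got1l1, within 10 Mb of Atp7b, was at least 718-fold higher (27.9 ± 12.6 CPM), Slc35f2, a solute carrier, at least 595-fold (23.1 ± 8.59 CPM), Mgst2 at least 397-fold and Syt14 at least 210.2-fold. Wfdc12 was at least 698-fold higher, or at least 137-fold without KO_drug 1, and Tex19.1 at least 377-fold, or at least 173-fold without KO_drug 1; limma with sample weights called neither (adjusted p = 0.123 and 0.117). Among the falls, Mapk4 was 31.8-fold lower. Tcf24 fell by 6.97 (SE 1.15), with 5 counts in KO_drug that all came from KO_drug 2, and by 10.65 without it and 6.22 without Het 1. Ccr3, a chemokine receptor of eosinophils, fell by 5.44 (SE 0.89), or 8.82 without KO_drug 2, and Dnaic1, a dynein chain of cilia, by 4.86 (SE 0.82), or 8.54 without KO_drug 1. Fam184a had 120 counts in Het and 2 in KO_drug, both in KO_drug 1, a ratio of levels of 59.1 (95% interval 16.0 to 494). The log2 change of Fam184a, -5.61 (SE 1.12), was -8.13 without KO_drug 1. Without KO_drug 2 for Tcf24 and Ccr3, or KO_drug 1 for Dnaic1 and Fam184a, the KO_drug group stood at 0. The changes given for these genes without those libraries are therefore not measured sizes. Bhlha15 fell by 4.09 (SE 1.06), but was not called without Het 4 (adjusted p = 0.0578), and its change was -4.82 without KO_drug 1.

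Fatty acid synthesis had 16 of 22 members higher adjusted over the list alone (camera adjusted p = 1.1e-09, and 0.143 with an estimated correlation), with Elovl6, a fatty acid elongase, 4.06-fold higher. The LXR targets had 13 of 19 (adjusted p = 2.7e-09, and 0.108 with an estimated correlation), with Scd1 14.0-fold and Fasn 5.29-fold higher. Fatty acid oxidation and PPAR alpha targets rose in 9 of 23 members (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.0141, and 0.868 with an estimated correlation), with Ehhadh, a peroxisomal bifunctional enzyme, 11.6-fold and Vnn1, a pantetheinase, 7.74-fold higher. p53 targets had 14 of 14 higher adjusted over the list alone (adjusted p = 1.4e-13, and 0.168 with an estimated correlation), with Phlda3 21.2-fold. Cell cycle genes had 14 of 27 (adjusted p = 6.1e-10, and 0.457 with an estimated correlation), with Aurka 8.08-fold higher. NRF2 targets had 9 of 20 higher and 2 lower (10 and 3 adjusted over the list alone; adjusted p = 0.000865, and 0.310 with an estimated correlation), with Gsta1 30.9-fold and Gstm3 14.5-fold higher. The stress list had 8 of 14 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.000354, and 0.211 with an estimated correlation), with Creld2 and Sdf2l1, proteins of the endoplasmic reticulum, 6.35-fold and 6.39-fold lower.

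Copper genes had 3 of 18 members higher and 2 lower (4 and 2 adjusted over the list alone) and were not called (adjusted p = 0.712), with a median of -0.03 against a mean of 0.57, and the median turned to 0.16 under total-count scaling. Slc30a1, a zinc exporter, was 2.57-fold higher and Slc31a1 2.05-fold lower. Bile acid genes had 2 of 19 higher and 6 lower (adjusted p = 0.131), with Abcc2, a canalicular exporter of conjugates, 2.06-fold and Acox2, an enzyme of bile acid side chains, 1.97-fold higher. P450s had 5 of 17 higher and 3 lower (adjusted p = 0.367; median -0.27 against a mean of 0.76), with Cyp2a4 47.9-fold and Cyp2c55 29.3-fold higher. Hepatocyte genes had 4 of 22 lower (2 lower and 2 higher under total-count scaling; adjusted p = 0.0637), Hnf4a by 1.73-fold. Nuclear receptors had 3 of 16 lower and 1 higher (1 and 1 under total-count scaling; adjusted p = 0.363), the latter Nr1i2, the xenobiotic receptor PXR, by 1.88-fold. Acute phase genes had 2 of 21 lower, Itih3 by 2.62-fold and Crp by 1.85-fold, with 1 higher (adjusted p = 0.423). Cholesterol genes had 3 of 25 lower and 1 higher (0 and 1 under total-count scaling, and 0 in edgeR adjusted over the list alone; adjusted p = 0.0305, and 0.868 with an estimated correlation). That list was not called without Het 2 (adjusted p = 0.0737), KO_drug 1 (0.0724) or KO_drug 4 (0.195). Male-biased genes had 5 of 11 lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0338, and 0.868 with an estimated correlation), Cyp7b1, a hydroxylase of sterols, 3.08-fold lower and Cyp4a12b 3.21-fold higher. Female-biased genes had 1 of 8 higher (1 adjusted over the list alone; adjusted p = 0.0443, and 0.868 with an estimated correlation). Without KO_drug 1 neither sex-biased list was called (adjusted p = 0.0724 and 0.159), nor without Het 2 (0.0737 for both), Het 3 (0.0520 and 0.0638) or KO_drug 4 (0.0726 and 0.0812), and the female-biased list also not without Het 1 (0.0755) or KO_drug 2 (0.108).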

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

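The tests of a hormone state, of sequencing depth, of the hepatocyte share and of the choice of scaling were chosen after the results were seen.

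In each comparison, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many genes in edgeR, the best result this check can give. The other splits mix the 2 groups, which widens the spread within each side, so their few calls do not measure the rate of false calls. The real splits called 5388 genes in KO vs Het, 2445 in KO_drug vs KO and 2640 in KO_drug vs Het, and the highest other splits 1, 3 and 2.

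Xist stood at 81.78 CPM in KO 5 and 17.83 CPM in KO 6 against a mean of 0.06447 CPM in Het, a signal in a gene outside the comparisons; KO 5 had little Y-linked RNA and KO 6 had Y-linked RNA at 72.6% to 116% of the mean of KO 2 and KO 4. In KO 6, 9 transcripts stood at 11.6% to 30.7% (median 20.8%) of their KO 5 level. They were chosen from these data as present in KO 5 and low in every library other than KO 5 and KO 6. They are therefore specific to KO 5 by choice, and are not a list of female genes fixed beforehand. A hormone state of a male liver is argued against by Xist, which in KO 6 was 41.98 times its highest level in the 8 Het and KO_drug libraries. RNA of a female liver in the KO 6 library is a candidate explanation: of 9415 genes with at least 200 counts in KO 5, 0.01062%, Hbb-bs alone, lay in KO 6 under 0.5 of the level that the Xist share would bring, but 5 of the other 10 libraries also stayed under the bound of 1% set beforehand, so the test separates weakly. Hbb-bs (155.8 against 0.1268 CPM) argues against KO 5 itself as the source unless its reads are counted all or none, and another female animal, an XXY animal and a mosaic stay open; the sex of the animals is not in the labels.

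Under total-count scaling the median of all genes in KO vs Het was 0.54 higher. Different depth is argued against by the ratio of mean totals, 1.021, with overlapping totals. The 100 most abundant genes, which took 48.2% of the counts in Het on average, may account for part of the shift, since without them its median was 0.2219. Without the 500 most abundant genes the median was 0.1243. The remaining shift stays open, as does a true rise of most transcripts per cell, which no spike-in tests here.

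Macrophage genes were higher and hepatocyte genes lower in KO vs Het. A lower share of hepatocytes acting alone would raise every other cell type alike. The macrophage score, however, rose by 1.947 more than the sinusoidal endothelial score on the log2 scale (SD 0.470 in KO and 0.546 in Het, n = 4 each, exact permutation p = 0.0286, the smallest possible). Both lists were picked with their changes known, so this p-value carries no weight as a test. The difference bears only on a lower share as the sole source. The choice of scaling is argued against as the whole source, since under total-count scaling the hepatocyte median was still -0.2692 and the macrophage median 2.209. A lower share of hepatocytes together with more macrophages, more macrophages alone, and changed transcription within cells stay open and were not tested.

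Groups of 4 values were checked for a library far from the other 3 by its gap over the range. Chance gives about 1 in 20 for normal values, but a group with counts in 1 library alone reaches a gap of 1 by construction. Of 404 groups, 24 held such a library, a number that can therefore not be set against 1 in 20. With the gap first, then the level in that library and the mean of the other 3 in CPM, these were Spink1 in KO_drug 1 (0.889; 17.46 and 3.022), Sult2a8 in Het 1 (0.836; 1404 and 859.1), Hnf4a in Het 3 (0.863; 956.2 and 798.5), Eda2r in KO 5 (0.854; 27.41 and 45.92), Phlda3 in KO_drug 2 (0.890; 3.335 and 8.197), Scd4 in KO 5 (0.968; 0 and 0.4767) and Lum in KO 4 (0.844; 33.0 and 17.35). Further ones were Arg1 in Het 1 (0.841, with 1402 and 1800), Creld2 in KO_drug 4 (0.845, with 23.1 and 13.69), Ppara in Het 3 (0.858, with 400.4 and 218.7), Vnn1 in Het 3 (0.875, with 8.253 and 4.241) and Itih3 in KO 6 (0.833, with 891.4 and 615.8). A gap of 1, with the other 3 libraries at 0, was found for Mmp8 in Het 2 (0.104 CPM), Gzmb in Het 4 (0.2551), Cd3d in Het 2 (0.2599), Slc2a4 in Het 3 (0.1058), Scd4 in Het 3 (0.582), Rab44 in Het 1 (0.1547), Kif5c in Het 2 (0.104), Tcf24 in KO_drug 2 (0.2606), Fam184a in KO_drug 1 (0.1009), Ccr3 in KO_drug 2 (0.2085) and Dnaic1 in KO_drug 1 (0.2523). The major urinary proteins took 16.58% of the counts of Het 2 and 12.42% on average in the other 3 Het libraries, a gap of 0.952.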

How the results depend on the processing

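KO 2 and KO 4 as the KO group, total-count scaling, leaving out the 100 most abundant genes, and the deposited FPKM were chosen after the results were seen. The count of genes called in KO vs Het stayed within 1.5 times of 5448 under all of these and under the alternatives chosen before (3693 to 7369), except that 2656 remained with a minimum of 1 on the log2 scale. That minimum left 1316 in KO_drug vs KO and 1373 in KO_drug vs Het. The genes behind these counts differed more. Of the 5448 genes, 64.96% were called again under total-count scaling, in either direction, and 665 had the opposite sign there. On FPKM, where 10797 genes were tested, 47.82% were called again and 753 had the opposite sign. Of the FPKM calls 93.23% were higher, against 56.48% in the main fit. KO_drug vs KO ranged from 1632 (without KO_drug 3) to 2935 (without KO_drug 1) when a library was left out, which also leaves fewer samples, and was 4255 under total-count scaling. Opposite calls ranged from 1142 (without KO 4) to 2151 (without KO_drug 1) when a library was left out, and were 2268 under the DESeq2 Wald test, 3421 under total-count scaling and 2964 on FPKM. In the last 2 settings the median of all genes was 0.54 and 0.39 in KO vs Het, and -0.36 and -0.25 in KO_drug vs KO. Since the KO libraries enter both comparisons with opposite sign, such a shift adds opposite calls by itself. The size of that part, and the cause of the other differences, were not tested. The change of Atp7b in KO_drug vs KO, 0.09 and not called, ranged from -0.2162 (without KO_drug 2) to 0.2786 (without KO_drug 3) and was -0.1052 with sample weights, -0.249 under total-count scaling and -0.0828 on FPKM; the cause was not tested. With an estimated correlation 0, 2 and 0 lists were called in the 3 comparisons. With equal animal numbers as a block (replicate block), KO 5 and KO 6 share their numbers with no other library. The block then fits each of them exactly, and KO rests on KO 2 and KO 4. Calls lost in this setting can therefore not be read as an effect of pairing alone. The block gave 3693, 1741 and 2516 genes and 1355 opposite calls, and ended 17 calls of single genes and 3 of lists. The lists were fatty acid synthesis (adjusted p = 0.0813) and female-biased genes (0.165) in KO vs Het and the stress list (0.207) in KO_drug vs KO, and the genes included Hlf (0.0585) in KO vs Het, Bhlha15 (0.0760) in KO_drug vs Het and, in KO_drug vs KO, Mcm4 (0.0752), Ogdhl, Asb11, Rab44, Cdh17 and Kif5c (0.0520 to 0.0810) and Slc2a4, whose change was 3.159 (SE 1.166, adjusted p = 0.113) in place of 5.23. No label says what equal numbers share: deviations of 8 equal-number pairs correlated at -0.0346 to 0.136, 3 of them over 0.1, and those of other pairs at -0.181 to 0.22, and not every library correlated best with its own number, so a pairing is neither shown nor excluded. Without genes shared between lists, 4 list calls ended: fatty acid synthesis (adjusted p = 0.123) and female-biased genes (0.419) in KO vs Het, and female-biased (0.721) and male-biased genes (0.257) in KO_drug vs Het. fry ended 6 list calls. In simulated data a change of 1 on the log2 scale was recovered in 50% to 58% of genes at this depth. Only 160 to 168 genes were called there, so the adjustment asked for a smaller unadjusted p than in the data. These shares therefore do not give the recovery in the real comparisons, where changes may still be missed. Other pseudocounts, filters on values and scalings planned for a file of normalized values were not run, since the file holds counts.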

Other observations

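Among LXR targets not named so far, chosen after their values were seen, Abcg5 and Abcg8, which together form the sterol exporter into bile, rose in KO_drug vs KO by 2.55 (SE 0.41, adjusted p = 0.0020) and 2.49 (SE 0.41, adjusted p = 0.0021) on the log2 scale. Srebf1, the transcription factor of lipid synthesis, rose by 2.79 (SE 0.45, adjusted p = 0.0020), Cyp7a1, the first enzyme of bile acid synthesis, by 2.22 (SE 0.47, adjusted p = 0.0063) and Abca1, a cholesterol exporter, by 1.09 (SE 0.26, adjusted p = 0.013; n = 4 per group, edgeR).

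Afp, H19, Igf2 and Gpc3 were chosen after their values were seen and belong to no fixed list. Afp, alpha-fetoprotein, went from 2.98 ± 1.31 CPM in Het to 132 ± 83.4 CPM in KO and 17.8 ± 5.99 CPM in KO_drug (mean ± SD, n = 4 each). H19, an imprinted RNA, stood at 7.391, 27.21, 436.8 and 224 CPM in KO 2, KO 4, KO 5 and KO 6, and at 0.3571 CPM or less in Het. Igf2, a fetal growth factor, and Gpc3, a glypican, rose by 4.14 (SE 0.80) and 4.48 (SE 0.82) in KO vs Het and fell by 4.56 (SE 0.82) and 4.45 (SE 0.82) in KO_drug vs KO. These rises were uneven as well: in the same order of KO libraries Igf2 stood at 1.29, 4.154, 22.62 and 17.03 CPM (up to 1.289 CPM in Het) and Gpc3 at 3.842, 22.87, 71.74 and 55.73 CPM (up to 3.352 CPM in Het).

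Lcn2 stood at 1934 and 2244 CPM in KO 2 and KO 4 and at 149.2 and 249.5 CPM in KO 5 and KO 6, and Saa3 at 228.9, 270.2, 8.376 and 14.2 CPM in the same order. Hbb-bs and Hbb-b1, 2 beta-globin genes, excluded each other, the lower of them standing at 1.805 CPM or less in each of the 12 libraries, for example with 379.4 and 0.2053 CPM in KO 2 and 0.1268 and 132.5 CPM in KO 6. Adnp and Dpm1-adnp stood at 29.65 and 0 CPM in KO 2 and at 0 and 43.82 CPM in KO 4, but both were counted in KO_drug 3 (19.36 and 22.62 CPM), Het 2 (9.304 and 29.58 CPM) and KO 6 (7.902 and 27.63 CPM).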
